A study of Rattus norvegicus with 4 samples.

How the data were processed

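Liver RNA of male Sprague-Dawley rats weighing 250 to 300 g was compared between ligation of the common bile duct and a sham operation, 12 h after surgery. Per the labels, total RNA of the 3 rats of a group was mixed, poly(A) RNA was purified, and cDNA labelled with Cy3 or Cy5 was hybridised to a glass slide array described as holding 1800 rat genes. Channel 2 held the ligation RNA on each of the 4 arrays. It carried Cy5 on arrays 1 and 3 and Cy3 on arrays 2 and 4.

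The values used are the log2 ratios deposited by the authors, 1 per probe and array, for 1936 probes. Scanning, background correction, normalization and any scaling are not given in the sources used here. The base of the logarithm is not stated either. It was taken as 2, so every log2 value and fold change printed here rests on that reading, and natural logarithms would make each log2 value larger. The medians of the deposited columns were -1.26, 0.43, -0.96 and 0.26 for arrays 1 to 4, so the columns had not been centred on a common median. No intensity or background value was used, the signal over background is therefore unknown, and precision rests on the number of arrays.

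The direction of the ratio is not stated. It was read as ligation over sham on every array, which is likely and rests on the channel order in the labels. A rule in the design called for reading the table as Cy5 over Cy3 if arrays of opposite dye orientation correlated below -0.3 over all probes. The 4 such pairs gave Pearson r = -0.45, -0.36, -0.35 and -0.28 across probes, which are not independent replicates, so 3 of 4 pairs met it. That rule assumed values already corrected for dye. It was set aside after seeing the data, because of the comparison of probes of the same gene given in the closing section. That comparison is descriptive and does not settle the direction, which therefore rests on the channel order. All results were recomputed under the other reading.

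Probe names came from a table of the array platform's annotation. Of the 1936 probes, 1432 had 1 gene symbol, 19 had several and 485 were unnamed in that table. Symbols were checked by gene number against a RefSeq gene table of assembly GRCr8, where 1429 matched with the same symbol and 3 did not match. No coordinates are printed because the array's build is not given in the sources used here. The unnamed probes showed that the slide was printed in 16 blocks of equal layout. The 288 spots at the 18 positions unnamed in every block were taken as control spots, an inference from their position, and left out of the tests.

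Each array was centred on the median of its 1936 values. Probes with the same single symbol were averaged per array, and the others stayed separate, which left 958 genes and 216 other probes. A linear model with a ligation term and a gene-specific dye term (1 where ligation was in Cy5, -1 where in Cy3) was fitted with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes) and Benjamini-Hochberg adjustment over the 1174 features. Calls were made at adjusted p under 0.05. The prior SD was 0.155 on 10.4 prior degrees of freedom, with 2 residual degrees of freedom per gene. A separate description without a p-value counted genes with a mean of at least 1.5-fold and the same sign on each of the 4 arrays. The calls on simulated data for 958 genes, with 200 changed genes in each of 20 runs, recovered 98.7% of genes changed 1.3-fold and 100% of those changed 1.5-fold, 2-fold or 3-fold, and 4.34% of calls were false. The simulated noise was independent, was drawn from the fitted variances, and had a dye effect of equal size on every array. These runs therefore check the fit and do not measure power or false calls in the real arrays.

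The design, including that rule, 23 gene lists and the genes to name, was fixed before the data were examined. The lists were bile acid synthesis, bile acid and organic ion transporters, cholesterol synthesis and uptake, cytochrome P450 and flavin monooxygenases, conjugation enzymes, acute-phase proteins, plasma proteins and apolipoproteins, fatty acid oxidation and ketogenesis, fatty acid and triglyceride synthesis, glucose and glycogen metabolism, amino acid metabolism and urea cycle, oxidative and metal stress, heat shock and endoplasmic reticulum stress, immediate-early and growth response, cell cycle, extracellular matrix and stellate cells, cholangiocytes, leukocytes and Kupffer cells, blood cells, endothelium, ribosomal proteins, respiratory chain, and proteasome. The 22 lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. In 20 simulated runs camera called the shifted list in all 20 and 0 of 416 unshifted lists. The simulated genes had independent noise, whereas correlations estimated from the data ran from 0.104 to 0.693 for the called lists. The runs therefore do not test camera on correlated genes. The same lists were also tested with an estimated correlation, with fry, and against 10000 random lists of the same size. The test with an estimated correlation rests on the 2 residual degrees of freedom per gene. It can hardly call any list, so its adjusted p does not decide between a shifted and an unshifted list.

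The genes named by rule were the up to 12 highest and 12 lowest genes past adjusted p with at least 1.5-fold and the same direction on every array, up to 3 members per list past adjusted p with the largest absolute means (or 2 values where none passed), and 14 genes always given where measured. Of those 14, Abcb11, Abcb1b, Abcc3, Alb, Hmox1 and Krt19 had no probe of that name in the annotation table used, and 1 is not reported here. Any other gene named was chosen after its values were seen, or is an example from a fixed list.

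The alternatives fixed with them were a fit with no dye term, values as deposited, quantile and scale normalization between arrays, 1 row per probe, a robust prior, each array left out in turn, each dye orientation alone, adjusted p under 0.01, an ordinary test without moderation, stricter size rules and other list tests. Alternatives chosen after seeing the data were control spots kept, centring on named probes, on probes with a high dye term or within print blocks, subtraction of a curve on the dye term, a prior with a trend on the dye term, the reading as Cy5 over Cy3, natural logarithms, probes with a low dye term left out, the probe with the highest dye term per gene, signs taken after removing the dye term, and random lists matched on the dye term. Requirements on the number of arrays per feature had no effect because no value was missing. A filter on dim probes fixed with them was not run because it needs intensities. With 1 row per probe, a gene counted as called if any of its probes passed, and its value was that of the probe with the largest effect. Counts under that alternative thus favour genes with several probes.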

Results

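The arrays compared liver RNA of rats 12 h after the common bile duct had been tied, which stops the flow of bile into the intestine, with liver RNA of rats whose duct was exposed but left open. RNA of 3 rats per group was mixed before labelling, and each of the 4 two-colour cDNA arrays carried both mixtures. The ligated pool was labelled with Cy5 on 2 arrays and with Cy3 on the other 2. Each array gave a log ratio for 1936 probes with no missing value, and 958 named genes were tested, 340 of them through more than 1 probe. The 4 arrays may be repeat hybridisations of the same pair of pools, so p-values measure only the spread between arrays, not between animals. The median standard error of a gene was 0.08 (0.0756) on the log2 scale. The number of arrays limits this precision.

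The comparison asked which liver transcripts differed between obstructed and open bile flow at 12 h. In the ligated pool, 4 of 5 measured genes of bile acid synthesis were lower (the enzymes Cyp7a1, Cyp8b1 and Cyp27a1 and the receptor Nr1h4). So were 4 of 6 transporters of bile acids and organic ions and 13 of 25 cytochrome P450 and associated genes. In fatty acid oxidation, 4 of 6 genes were lower. With probes averaged per gene, carbonic anhydrase Car3 was the lowest gene, 5.88-fold lower (log2 -2.55 ± 0.08, SE, 4 arrays). The fatty acyl-CoA synthetase Acsl1 followed at 3.88-fold lower (log2 -1.96 ± 0.08), then the drug-metabolising enzyme Cyp1a2 at 3.64-fold lower (log2 -1.86 ± 0.08). A single probe of Cyp8b1 was lower than either probe of Car3, at -3.04 against -2.57 and -2.54. The highest gene was the fatty acid-binding protein Fabp5, 3.09-fold higher (log2 1.63 ± 0.07). These directions and ranks take the table as ligation over sham on every array, which is likely from the channel order in the labels but is not stated (read as Cy5 over Cy3, Car3 would be at 0.65 and Fabp5 at 0.46), and the folds take the logarithms as base 2.

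At limma's Benjamini-Hochberg adjusted p under 0.05, 260 of the 958 genes differed, 112 higher and 148 lower in the ligated pool, and 698 did not pass. At 1.5-fold or more, 12 of the called genes were higher and 44 lower, and at 2-fold or more 3 were higher and 10 lower. By size and sign alone, 36 genes had a mean of at least 1.5-fold and the same sign on all 4 arrays, 9 higher and 27 lower. All values are relative to the median of each array. Without that centring every gene moved by about -0.38 and the split of calls became 11 higher and 791 lower, while 22 of the 74 genes set out for these tests lost their call and 11 changed sign. Of 44 list members called higher with centring, only 4 stayed called higher without it (Anxa5, Cyp2c22, Nr0b2 and Scd). Calls in the higher direction thus rest on the zero point for the other 40 list members, and a downward shift cannot test the lower ones. With centring on the probes in the upper quartile of the dye term the split was 122 higher and 85 lower, and 9 of the 74 genes lost their call, all of them lower (A2m, Ccl5, Cd53, Cdk1, Col1a1, Cpt1a, Kdr, Pdia4 and Pim3). Read as Cy5 over Cy3, the same table called 747 genes, with 196 higher and 58 lower at 1.5-fold, and 119 of the 260 genes were then called in the opposite direction.

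**Figure D1:**
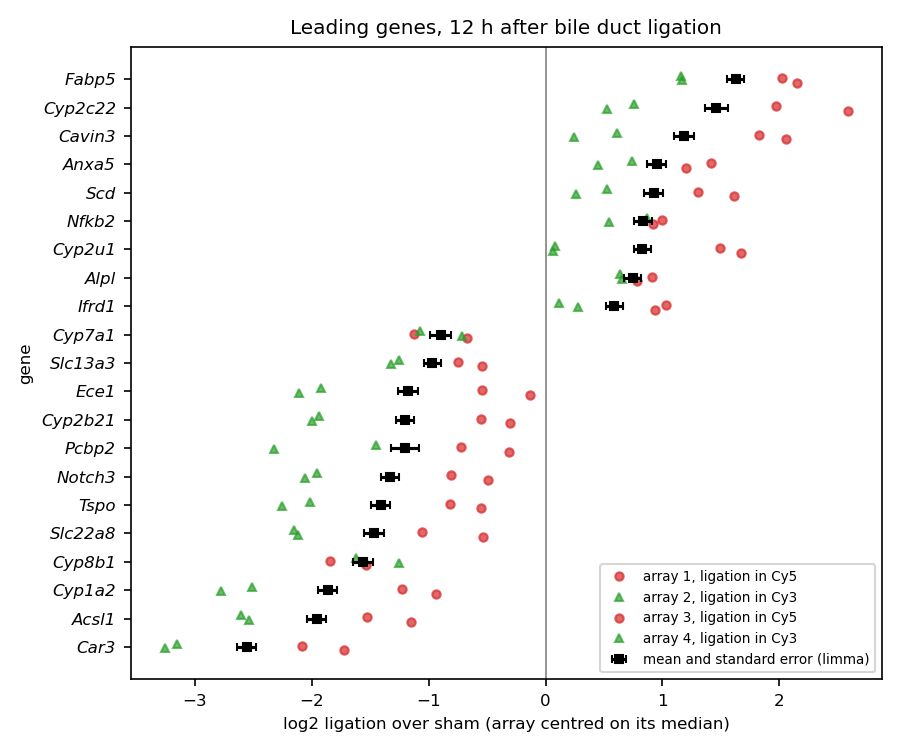
Log2 ratio of ligation over sham (horizontal axis) for the 21 leading genes (vertical axis), with red circles for the 2 arrays with ligation in Cy5, green triangles for the 2 with ligation in Cy3, and black squares with bars for the limma mean and standard error. Means run from -2.55 for Car3 to 1.63 for Fabp5, and the 4 arrays lie on the same side of 0 for each gene, as the rule that chose the genes required.

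Besides Fabp5, the leading genes in the higher direction were Cyp2c22 (log2 1.46 ± 0.10), Cavin3, a protein of the membrane pits called caveolae (1.18 ± 0.08), the phospholipid-binding annexin Anxa5 (0.95 ± 0.08) and the stearoyl-CoA desaturase Scd (0.93 ± 0.08). The NF-kappa-B subunit Nfkb2 was 0.83 ± 0.08, Cyp2u1 0.83 ± 0.07, alkaline phosphatase Alpl, a classical serum marker of cholestasis, 0.75 ± 0.07, and the interferon-related regulator Ifrd1 0.59 ± 0.07. Their limma adjusted p ranged from 5.98e-09 for Fabp5 to 5.28e-05 for Ifrd1. The call of Ifrd1 was lost without centring (0.21, adjusted p = 0.0757). The 3 probes of Cyp2c22 lay between 1.36 and 1.52. Cytochrome P450 cDNA probes can bind related transcripts, so values of single members of that family are uncertain.

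Among the lowest genes, the organic anion transporter Slc22a8 was at -1.47 ± 0.09, the mitochondrial cholesterol-binding protein Tspo at -1.41 ± 0.08, the receptor Notch3 at -1.33 ± 0.08, the RNA-binding protein Pcbp2 at -1.20 ± 0.12, Cyp2b21 at -1.20 ± 0.08 and the endothelin-converting enzyme Ece1 at -1.18 ± 0.08. The dicarboxylate transporter Slc13a3, measured by 5 probes, was at -0.97 ± 0.07, and its probes ranged from -1.19 to -0.69. Each of these 7 genes was lower on all 4 arrays, which the rule that chose them required. Their limma adjusted p lay between 4.7e-08 for Tspo and 8.12e-06 for Pcbp2.

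All 5 measured genes of bile acid synthesis passed, 4 lower and 1 higher, and the counts were equal when adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of the classical pathway, was at -0.90 ± 0.09. Cyp8b1, the sterol 12-alpha-hydroxylase that directs synthesis to cholic acid, was at -1.56 ± 0.09, but its probes differed, at -3.04 and -0.09. Cyp27a1, the sterol 27-hydroxylase of the alternative pathway, was at -0.66 ± 0.08, and the bile acid receptor Nr1h4 (FXR) at -0.64 ± 0.09. The higher gene was Nr0b2 (SHP), a repressor that bile acids induce through FXR, at 0.65 ± 0.09. The list's median was -0.66, lower than other genes by camera (adjusted p = 0.0215), with adjusted p = 0.739 with an estimated correlation. Without array 1 the camera adjusted p was 0.0672 (median -0.74), and without array 3 it was 0.0577 (median -0.59).

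Of 6 transporters of bile acids and organic ions, 4 were lower and 1 higher, and adjusted over the list alone 5 were lower and 1 higher. Slc10a1 (NTCP), the sodium-dependent bile acid uptake carrier of the sinusoidal membrane, was at -0.76 ± 0.07, and the organic anion carrier Slco2b1 at -0.57 ± 0.07. The efflux pump Abcc4 was at -0.30 ± 0.08. Abcc2 (MRP2), the canalicular exporter of conjugated bilirubin, was higher at 0.30 ± 0.08, but was at -0.09 without centring and lost its call without array 1 (0.19, adjusted p = 0.0976) or array 2 (0.27, adjusted p = 0.0753). Camera gave a lower list (median -0.44, adjusted p = 0.0185), with adjusted p = 0.739 with an estimated correlation. A probe shared by Slco1a6, Slco1a5 and Slco1a1 stayed outside the list because it had several symbols, and was at -0.77 (limma adjusted p = 5.27e-06).

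Of 25 cytochrome P450, flavin monooxygenase and associated genes, 13 were lower, 3 higher and 9 did not pass, and adjusted over the list alone 14 were lower and 3 higher. The lower members included Cyp1a2 (-1.86), the fatty acid hydroxylase Cyp4f4 (-0.88 ± 0.10), Cyp3a23-3a1 (-0.70 ± 0.09), Cyp2e1 (-0.37 ± 0.07, with 7 probes from -1.36 to 0.14) and Por, the reductase that passes electrons to microsomal P450 enzymes (-0.24 ± 0.07, with 5 probes from -0.37 to -0.041). The higher members were Cyp2c22, the soluble epoxide hydrolase Ephx2 (0.49 ± 0.08, but 0.11 and not called without centring) and Cyp2c12 (0.34 ± 0.07, with 4 probes from -0.21 to 1.32). Cyp2c12 was at -0.046 without centring and also not called. The camera test gave a lower list (median -0.23, adjusted p = 0.0185), with adjusted p = 0.739 with an estimated correlation, and 0.076 without array 4 (median -0.23). Of 7 conjugation enzymes, 3 were lower, among them the glutathione transferases Gstm2 (-0.82 ± 0.10) and Gsta2 (-0.46 ± 0.08), and 2 higher, among them Mgst1 (0.40 ± 0.08, but 0.02 (0.023) without centring), with camera adjusted p = 0.6. Adjusted over the list alone, 4 were lower and 2 higher. Probes with several symbols stayed outside these lists. Among those past adjusted p at 1.5-fold or more, probes shared by Sult2a2 and Sult2a1 were at -1.19, -1.03 and -1.01. A probe shared by Gstp2 and Gstp1 was at -0.67, while probes shared by Cyp4a3 and Cyp4a2 were higher, at 0.61 and 0.64.

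Of 6 genes of fatty acid oxidation, 4 were lower and 2 did not pass, and adjusted over the list alone 5 were lower. Besides Acsl1, the lower members were Echs1, an enoyl-CoA hydratase (-0.46 ± 0.08), Cpt1a, the carnitine transferase that controls entry of fatty acids into mitochondria (-0.30 ± 0.08), and Hadhb (-0.21 ± 0.07, with probes at -0.42 and -0.0068). Cpt1a lost its call without array 4 (-0.27, adjusted p = 0.0823) or array 3 (-0.24, adjusted p = 0.0546), and its probes were at -0.65 and 0.05. Camera gave a lower list (median -0.26, adjusted p = 0.0185), with adjusted p = 0.739 with an estimated correlation. In fatty acid and triglyceride synthesis, Scd and the fatty acid synthase Fasn (0.50 ± 0.07, but 0.12 without centring, adjusted p = 0.252) were higher, the hepatic lipase Lipc (-0.74 ± 0.09) was lower, and 5 of 8 members did not pass (camera adjusted p = 0.259). Adjusted over the list alone the counts were again 2 higher and 1 lower. Of 4 genes of cholesterol synthesis, the mevalonate kinase Mvk was higher (0.33 ± 0.08, but -0.05 without centring) over all genes and over the list alone, and 3 did not pass (camera adjusted p = 0.958). Without array 3 the call of Mvk was lost (0.25, adjusted p = 0.0514).

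**Figure D2:**
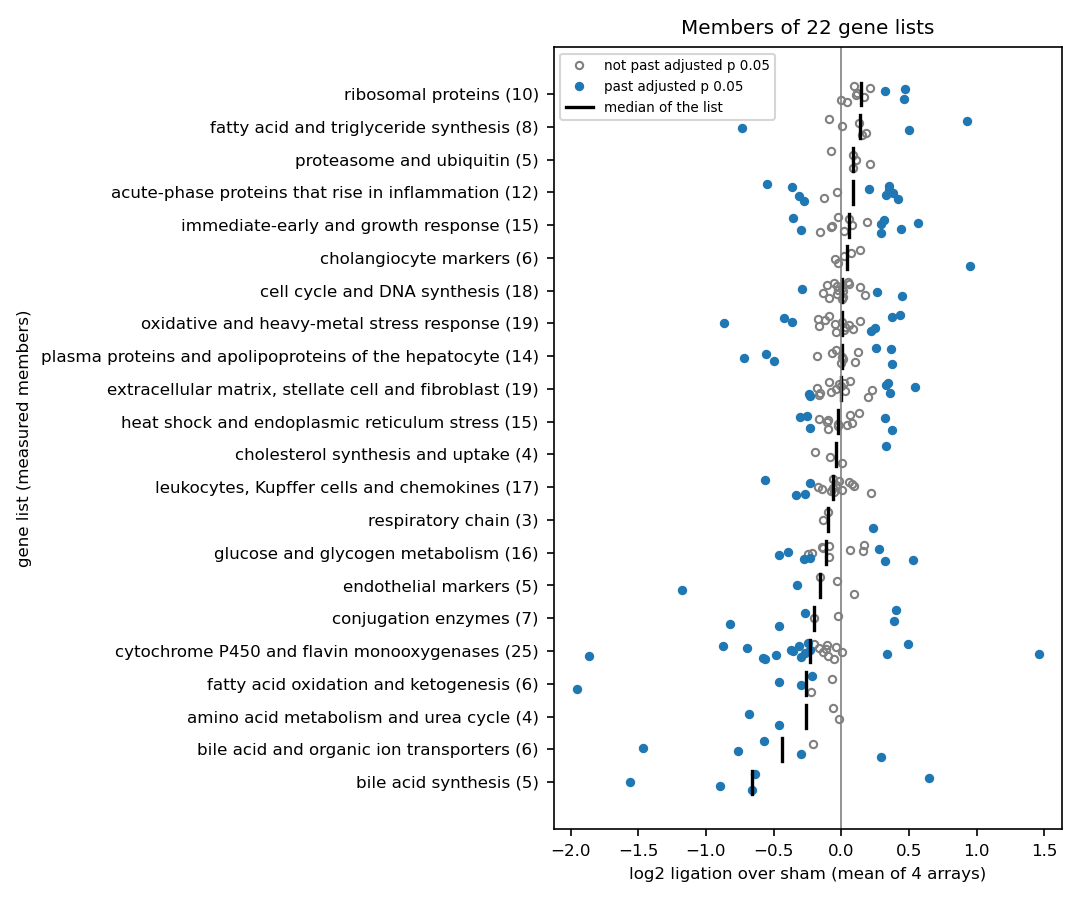
Log2 ratio of ligation over sham (horizontal axis, mean of 4 arrays) of each measured member of the 22 tested gene lists (vertical axis, number of members in brackets), with filled points past limma adjusted p under 0.05, open points not past it, and a bar at each list's median. Medians run from -0.66 for bile acid synthesis to 0.14 for ribosomal proteins, whose median was -0.24 without centring.

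Acute-phase proteins moved both ways, with 6 of 12 higher, 4 lower and 2 not past the test (camera adjusted p = 0.6). The counts adjusted over the list alone were equal. Complement C3 (0.42 ± 0.08) and the inter-alpha-trypsin inhibitor chain Itih3 (0.38 ± 0.08) were among the higher members, but without centring they were at 0.04 (0.037, adjusted p = 0.699) and 0.0021 (adjusted p = 0.981). The C1 inhibitor Serping1 (-0.55 ± 0.09) was lower, and so was A2m (-0.28 ± 0.08), a major acute-phase protein of the rat, whose call was lost without array 3 (-0.24, adjusted p = 0.11) or array 4 (-0.20, adjusted p = 0.263). Of 14 plasma proteins and apolipoproteins, 3 were higher, including Apoa1 (0.38 ± 0.08, but -0.0039 without centring), and 3 were lower, namely Azgp1 (-0.72 ± 0.08), Igfals, the carrier subunit of circulating IGF complexes (-0.56 ± 0.07), and Apoc1 (-0.50 ± 0.08), with camera adjusted p = 0.958 and equal counts over the list alone.

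In glucose metabolism, 3 of 16 genes were higher (Eno1 0.53 ± 0.08, Aldoa 0.32 ± 0.08 with probes at 0.65 and -0.01 (-0.012), and Pgam1 0.28 ± 0.07), none of them called without centring, and 4 were lower, among them the fructokinase Khk (-0.46 ± 0.08) and the pyruvate dehydrogenase kinase Pdk2 (-0.39 ± 0.08). Adjusted over the list alone 3 were higher and 6 lower (camera adjusted p = 0.84). Of 4 genes of amino acid metabolism, Fah, the last enzyme of tyrosine breakdown (-0.68 ± 0.09), and Agxt (-0.46 ± 0.08) were lower, over all genes and over the list alone, and 2 did not pass (camera adjusted p = 0.259).

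Stress genes went both ways. Of 19 oxidative and metal stress genes, the metallothionein Mt1 (-0.87 ± 0.10), Sod1 (-0.42 ± 0.08) and Nqo1 (-0.37 ± 0.08) were lower, and 4 were higher, among them the thioredoxin Txn1 (0.43 ± 0.09) and the mitochondrial Sod2 (0.37 ± 0.09, with probes at 0.80 and -0.06), neither called without centring, with camera adjusted p = 0.958. Of 15 heat shock and endoplasmic reticulum stress genes, 3 were lower, including Pdia4 (-0.31 ± 0.08), and 2 higher, Asns (0.37 ± 0.08) and Pdia3 (0.32 ± 0.08), which were at -0.01 (-0.0069) and -0.06 without centring, with camera adjusted p = 0.962. Among 15 immediate-early and growth response genes, 5 were higher and 2 lower. Myc was at 0.56 ± 0.08, Egr1 at 0.44 ± 0.09 and Nfkbia, the inhibitor of NF-kappa-B, at 0.32 ± 0.07, while the kinase Pim3 was at -0.35 ± 0.08 (camera adjusted p = 0.259). Without centring, Myc was at 0.18 (adjusted p = 0.13), Egr1 at 0.06 (0.056, adjusted p = 0.663) and Nfkbia at -0.06 (-0.064), none of them called. Adjusted over the list alone, the counts were 4 higher and 3 lower for oxidative stress, 2 and 3 for heat shock, and 6 and 2 for the growth response. Calls were lost without array 3 for Pdia4 (-0.23, adjusted p = 0.0582) and without array 4 for Pdia3 (0.28, adjusted p = 0.0589) and Pim3 (-0.25, adjusted p = 0.109). Of 18 cell cycle genes, cyclin D1 (Ccnd1, 0.45 ± 0.07, but 0.07 (0.069) without centring, adjusted p = 0.532) and Ccng1 (0.27 ± 0.09, but -0.12 without centring, and called in 1 of 3 probes) were higher, Cdk1 was lower (-0.29 ± 0.07, with 5 probes from -0.85 to -0.01, the last -0.0064), and 15 did not pass (camera adjusted p = 0.618). Adjusted over the list alone 1 was higher and 1 lower. The call of Ccng1 was lost without array 1 (0.15, adjusted p = 0.225), or array 4 (0.22, adjusted p = 0.187), and that of Cdk1 without array 2 (-0.26, adjusted p = 0.0851) or array 3 (-0.24, adjusted p = 0.056).

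Of 19 matrix and stellate cell genes, 4 were higher and 2 lower, over all genes and over the list alone (camera adjusted p = 0.508). The growth factor Pdgfa was at 0.55 ± 0.08 (0.16 without centring, adjusted p = 0.19), the protease inhibitor Timp1 at 0.35 ± 0.08 (-0.03 without centring), and Col1a1 at -0.23 ± 0.07 (probes at -0.42 and -0.051), a call lost without array 2 (-0.24, adjusted p = 0.12), array 3 or array 4. Lamb2 was at 0.36 ± 0.12, and its call was lost without array 1 (0.13, adjusted p = 0.265), with quantile normalization (adjusted p = 0.0515), with a robust prior (0.0594), and with print-block centring (0.165) or the subtracted curve (0.063), both added. Of 6 cholangiocyte markers, Anxa5, which other cells also express, was higher over all genes and over the list alone, and 5 did not pass, including osteopontin (Spp1, 0.14 ± 0.07), with camera adjusted p = 0.27. Of 17 leukocyte and Kupffer cell genes, 4 were lower and 13 did not pass, with equal counts over the list alone and camera adjusted p = 0.508. The cytokine Tnf was at -0.57 ± 0.08, Ccl5 at -0.33 ± 0.07 and Cd53 at -0.27 ± 0.08, of which Cd53 lost its call without array 2 (-0.27, adjusted p = 0.0726), array 3 or array 4, and Ccl5 without array 2 (-0.28, adjusted p = 0.0574). Of 5 endothelial markers, Ece1 and Kdr (-0.33 ± 0.09) were lower over all genes and over the list alone, with camera adjusted p = 0.259, and the call of Kdr was lost without array 1 (-0.26, adjusted p = 0.149) or array 2. The platelet factor Pf4, the 1 blood cell marker measured, was at -0.02 ± 0.08.

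Ribosomal proteins were the list that camera gave as higher (adjusted p = 0.0185), with adjusted p = 0.739 with an estimated correlation, 0.0921 without array 2 and 0.107 without array 4. The median was 0.14, but -0.24 without centring. Of 10 members 3 were higher, none of them called without centring, namely Rpl6 (0.47 ± 0.07), a probe named for the pseudogene Rpl17-ps16 (0.46 ± 0.09), which may share sequence with its parent gene, and Rpl41 (0.32 ± 0.07, with probes at 0.44 and 0.20, but -0.06 without centring). Adjusted over the list alone 4 were higher. Without centring, camera called none of the 22 lists. With centring, fry, which asks whether the genes of a list move one way on balance, gave adjusted p of at least 0.0717. In the respiratory chain, Atp5if1, an inhibitor of the ATP synthase, was higher over all genes and over the list alone (0.23 ± 0.07, with probes at 0.16 and 0.30, but -0.15 without centring) and 2 did not pass (camera adjusted p = 0.958). Leaving out any 1 array ended that call. The list's median was -0.10 and its mean -0.00073, against an upward camera direction. None of 5 proteasome genes passed limma's test over all genes or over the list alone, with the largest values at 0.21 ± 0.08 for Psmc5 and 0.11 ± 0.08 for Psmd2 (camera adjusted p = 0.477). Psmc5 was called, however, with 1 row per probe (0.34, adjusted p = 0.0079), through its probe of largest effect, while its other probes were at 0.07 and 0.23. It was also called without array 3 (0.28, adjusted p = 0.0338) and under 4 alternatives chosen after seeing the data.

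Read as ligation over sham, the table had a dye term past adjusted p in 747 of the 958 genes and a ligation term in 260, and the reading as Cy5 over Cy3 exchanges these counts. Arrays of the same orientation correlated at Pearson r = 0.91 (arrays 1 and 3) and 0.935 (arrays 2 and 4) across 1174 features, which are not independent replicates. Arrays of opposite orientation gave -0.439, -0.355, -0.298 and -0.224. Means that held both orientations equally gave r = 0.905 (arrays 1 and 2 against 3 and 4) and 0.86 (arrays 1 and 4 against 2 and 3). The SD of the ligation term over features rose from 0.08 (0.0769) in the lowest quartile of the dye term to 0.51 in the highest, where 41 genes were called higher and 66 lower.

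**Figure D3:**
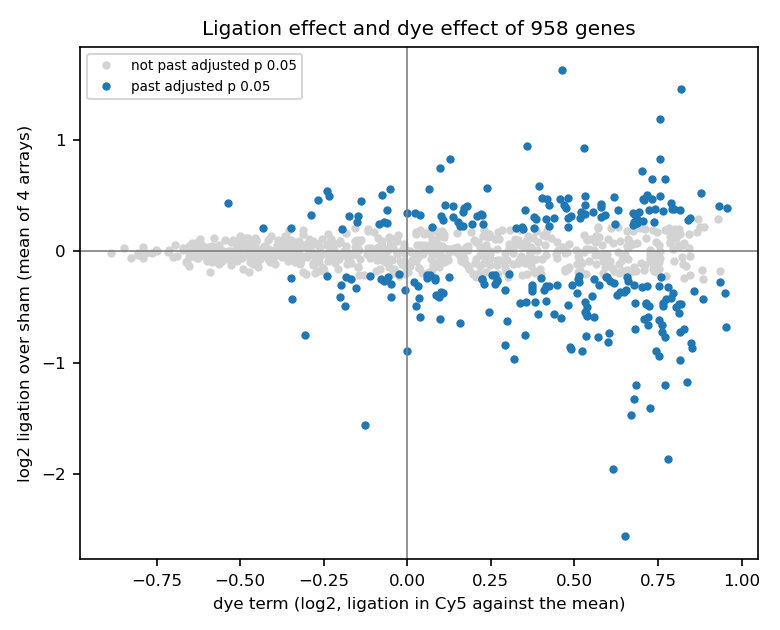
Ligation term (vertical axis, log2 ligation over sham, mean of 4 arrays) against dye term (horizontal axis, log2) of 958 genes, with blue points past limma adjusted p under 0.05 and grey points not past it. Ligation terms spread more widely at higher dye terms, with an SD of 0.48 over the 240 genes of the highest quartile against 0.08 (0.0796) over the 240 of the lowest.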

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

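The probe comparisons and the count over sign patterns were chosen after the results they bear on were seen. The tests of the zero point and of the subtracted curve were written before their results were seen.

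Probes outside the named genes also differed. Of the 216 probes with no symbol or several, 27 passed limma's adjusted p with at least 1.5-fold, 18 lower and 9 higher. The lowest unnamed one was probe 385 at -2.09 and the highest probe 1510 at 1.46. Among the spots taken as controls, those at positions 108 to 110 of each block had a centred mean of 0.885 (0.68, 0.39, 0.55 and 0.40 as deposited on arrays 1 to 4).

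Arrays of opposite dye orientation correlated below 0, which a table still running as Cy5 over Cy3 would produce. Under that reading, however, 85 of 263 genes with at least 2 called probes (32.3%) had probes called in opposite directions, against 7 of 57 (12.3%) under ligation over sham (two-sided Fisher's exact p = 0.002). Both counts come from the same multi-probe genes and arrays, so the independent groups that this test assumes are not given. The readings also call unlike numbers of genes, 747 and 260. The comparison is therefore descriptive and does not settle the direction. In 111 of 153 genes with several probes and a called probe (72.5%), the probe with the higher dye term had the larger ligation effect (two-sided exact binomial p = 2.25e-08). That does not test dye bias that follows spot brightness, because how the dye term relates to brightness is unknown. Features in the lowest quartile had dye terms of -0.886 to -0.322. Spots taken as controls at positions 111 to 116 and 102 to 104 lay in that range (-0.778 and -0.625). Their centred means were 0.0065 and 0.0245. Controls at positions 108 to 110 and 89 to 91 had high dye terms (0.835 and 0.722) and means of 0.885 and 0.382. Spot identity is unknown. Of the 237 genes in the lowest quartile, 3 were called higher and 2 lower. Those that did not pass may be unchanged or undetected, which was not tested. Brightness was not measured here, dye bias that follows it stays open, and misnamed or cross-binding probes stay open for the 7 genes.

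More genes were lower than higher at 1.5-fold (44 against 12) with the table read as ligation over sham, while the reading as Cy5 over Cy3 turned the balance (58 lower, 196 higher). If the choice of zero were the cause, other centrings should even the counts, but the smallest ratio of lower to higher genes over the 3 centrings tried (named probes, upper quartile of the dye term, print blocks) was 2.06. The median gene moved by only 0.033, 0.077 and 0.011 under these centrings, in that order. The test therefore covers only zeros that close and does not decide whether the zero point is the cause. Larger upward shifts were not tried. Subtracting a curve on the dye term gave a ratio of 4.36 (48 lower, 11 higher). The curve moved no gene by more than 0.06 (0.0598), however, too little to even the counts. It therefore decides nothing about dye bias left in the mean. A dye effect of equal size on every array cancels in this mean, which holds 2 arrays per orientation. Dye bias that differs between arrays does not cancel, and it stays open. A response of the ligated livers also stays open as a hypothesis, and so does a difference between the pools from handling or from single animals, which pooling leaves untested.

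For the count of 260 genes, the 8 sign patterns of the 4 arrays are too few for a share under 0.05. A count at least as high came from 2 of the 8, the real pattern and the one that follows dye orientation, which was the highest other at 747 and is a structure of the arrays.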

How the results depend on the processing

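The count of 260 genes stayed within 1.5 times under quantile (241) and scale (275) normalization, 1 row per probe (310), a robust prior (258), adjusted p under 0.01 (175) and with each array left out in turn (191 to 240, with 180 to 211 of the 260 genes still called in the same direction). Among alternatives chosen after seeing the data, it was 207 to 287 with control spots kept, other centrings apart from none, a subtracted curve, a trend in the prior, the lower dye terms left out or the probe with the highest dye term per gene. Without array 4, 74 genes were higher, against 112. The depth of signal is unknown, so the limit is the spread of 4 arrays of pooled RNA. In every case below without a stated reason the cause was not tested.

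With no dye term limma called 0 genes, since dye variation then enters the error, with 52 at unadjusted p under 0.05. The ordinary test on 2 residual degrees of freedom called 0, with 231 at unadjusted p under 0.05. Both then gave 0 higher and 0 lower at 1.5-fold. Values as deposited gave 802 genes, because the zero moved by -0.38, with 3 higher and 165 lower at 1.5-fold. With 1 row per probe, 21 genes were higher at 1.5-fold. Natural logarithms (an added alternative) would make it 40 higher and 78 lower. The reading as Cy5 over Cy3 (added) gave 747 genes, with 196 higher and 58 lower at 1.5-fold, a dye effect in 260 and r = 0.942 between dye-balanced means. Leaving out probes below the median dye term (added) gave r = 0.952.

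The size rule gave 127 genes as deposited, 239 from arrays with ligation in Cy5 alone, 279 from those with ligation in Cy3 alone (both with dye effects uncancelled), 13 at 2-fold and 7 at 1.5-fold on each array. It gave 226 as Cy5 over Cy3, 55 with natural logarithms and 56 with signs taken after removing the dye term (all added). It ranged from 34 to 56 with 1 array left out, the highest without array 1.

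The 5 list calls became 0 as deposited, 0 with an estimated correlation (0 lists at unadjusted p under 0.05), 0 with fry (8 at unadjusted p under 0.05, lowest adjusted p 0.0717), 1 as Cy5 over Cy3, 2 without probes below the median dye term, 8 by random lists and 3 to 4 with 1 array left out. As deposited, medians and camera adjusted p were -1.04 and 0.439 for bile acid synthesis, -0.82 and 0.18 for transporters, -0.61 and 0.355 for P450 genes, -0.64 and 0.118 for fatty acid oxidation, and -0.24 and 0.118 for ribosomal proteins. With an estimated correlation the medians stayed at -0.66, -0.44, -0.23, -0.26 and 0.14, with camera adjusted p = 0.739 for each. On 2 residual degrees of freedom that test had little power, so these values do not decide about the lists. As Cy5 over Cy3 they were 0.16, 0.54, 0.48, 0.30 and 0.53. Quantile normalization gave -0.61 for bile acid synthesis (adjusted p = 0.0569). Without probes below the median dye term, transporters were at -0.46 and P450 genes at -0.26 (adjusted p = 0.13 for both) and ribosomal proteins at 0.27 (0.145). Ribosomal proteins were also no longer called with no dye term (0.14, adjusted p = 0.0733), control spots kept (0.14, 0.111) or the probe with the highest dye term (0.16, 0.0524). Ligation in Cy5 alone gave 0.047 for transporters, 0.099 for P450 genes and 0.75 for ribosomal proteins. Ligation in Cy3 alone gave -0.93, -0.60 and -0.25 for these and -0.45 for fatty acid oxidation. With 1 array left out, medians ranged from -0.75 to -0.59 for bile acid synthesis, -0.30 to -0.17 for P450 genes and 0.10 to 0.24 for ribosomal proteins, while transporters and fatty acid oxidation stayed called.

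Of the 74 named genes, values as deposited turned the sign of Abcc2 -0.086, Asns -0.0069, Atp5if1 -0.15, Ccng1 -0.12, Lamb2 -0.020, Mvk -0.054, Pdia3 -0.059, Psmd2 -0.27, Rpl41 -0.060 and Timp1 -0.034, and of Psmc5 -0.17, not called in either. Arrays with ligation in Cy5 alone, where the dye effect stays in the value, turned Agxt 0.22, Apoc1 0.31, Azgp1 0.039, Ccl5 0.042, Cd53 0.0031, Cyp27a1 0.057, Echs1 0.30, Egr1 -0.10, Fah 0.27, Gstm2 0.023, Khk 0.25, Pdia4 0.19, Pdk2 0.23, Pim3 0.019, Serping1 0.26 and Sod1 0.46. Arrays with ligation in Cy3 alone turned Abcc2 -0.39, C3 -0.11, Ccng1 -0.41, Eno1 -0.35, Fasn -0.032, Itih3 -0.36, Lamb2 -0.40, Mgst1 -0.53, Nr0b2 -0.084, Pdia3 -0.36, Rpl17-ps16 -0.25, Rpl41 -0.17, Rpl6 -0.26 and Txn1 -0.36, and of the genes not called in the main fit Pf4 0.40, Psmc5 -0.57 and Psmd2 -0.55. The reading as Cy5 over Cy3 gave A2m 0.021, Acsl1 0.61, Agxt 0.68, Apoc1 0.80, Asns -0.062, Azgp1 0.76, Car3 0.65, Ccl5 0.37, Ccnd1 -0.14, Cd53 0.27, Cdk1 0.23, Cyp1a2 0.78, Cyp27a1 0.72, Cyp2b21 0.77, Cyp4f4 0.49, Ece1 0.84, Echs1 0.76, Egr1 -0.54, Fah 0.95, Gsta2 0.38, Gstm2 0.85, Igfals 0.54, Khk 0.71, Lipc 0.60, Mt1 0.85, Notch3 0.68, Pcbp2 0.68, Pdgfa -0.24, Pdia4 0.49, Pdk2 0.63, Pim3 0.37, Serping1 0.81, Slc10a1 0.53, Slc13a3 0.32, Slc22a8 0.67, Slco2b1 0.54, Sod1 0.89, Timp1 -0.00049, Tnf 0.44 and Tspo 0.72. With 1 array left out, 5 to 8 of the named genes lost their call and none of the called ones changed sign, while Pf4, not called, was at 0.054 without array 3. Calls were also lost under quantile normalization (Ccng1 and Lamb2), a robust prior (Lamb2) and, among added alternatives, centring on named probes (Col1a1), on the upper quartile of the dye term (9 genes) or within print blocks (A2m, Abcc2, Ccng1 and Lamb2), a subtracted curve (Ccng1 and Lamb2) and a trend in the prior (Mgst1).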

Other observations

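Several genes outside the fixed lists also passed limma's test at 1.5-fold or more. They were chosen after their values were seen. In the ligated pool the growth factor receptor Fgfr3 was at -0.90, the neonatal Fc receptor Fcgrt at -0.89, the vasopressin receptor Avpr1a at -0.86 and the monoamine oxidase Maob at -0.84 (log2). The prostaglandin receptor Ptger1 was at -0.77, with 3 probes from -1.18 to -0.04, and the carbonic anhydrase Car2 at -0.75, with probes at -1.62 and 0.11. The aldehyde dehydrogenase Aldh2 was at -0.70, with 3 probes from -0.76 to -0.67. In the other direction, the nucleolar protein Npm1 was at 0.73 and the oxysterol receptor Nr1h2 at 0.65. They stand for no group of genes, and no enrichment was tested.

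Probes called in opposite directions occurred for the 7 genes Ccl6, Cdc23, Cyb5a, Cyp2c6v1, Gc, Hadha and Ifngr2, so their averaged values hide differences between probes. The spots at positions 89 to 91 of each block had deposited means of -0.0027, 0.0049, -0.0020 and 0.0014 on arrays 1 to 4, near 0 on each. After centring their mean was 0.382, so the deposited zero and the zero used here differ at these spots. Their identity is unknown, and whether the deposited values had been set to 0 on them was not tested. The spots at positions 111 to 116 had deposited means of -1.92, 1.21, -1.83 and 1.04, with the sign following dye orientation.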
